A study of Mus musculus with 18 samples.

How the data were processed

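Gene expression was measured by sequencing polyadenylated RNA from 3T3-L1 cells in 18 libraries, 3 each from Control, MCE1, MCE2, Day4, Day6 and Day8. Per the labels' protocols, cells 2 days past confluence received insulin, dexamethasone and IBMX for 48 h and then medium with insulin, changed every 2 days. The deposited values are TPM per gene, 1 table per library, with the gene's position. Per the submitters' processing notes, reads were checked with FastQC, trimmed with cutadapt, aligned with HISAT2 to the mm9 build and quantified with StringTie, with no versions given. The gene annotation used and any filter on the listed genes are not stated. The listed TPM of a library summed to 869497 to 880273, so part of each library is not in the listed values. Read counts and depth are not given and were not used here, so counting error could not be separated from the spread between replicates, which sets the precision of every value below.

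Each library's table held the same 25209 gene names, each once. In Control replicate 1, 12 genes were listed at another locus than in the other 17 libraries and were left out. Its table is also the only 1 that writes chromosomes without a prefix. Whether it was made with another annotation is not stated, and it enters every comparison with Control. For 867 genes the recorded end differed between libraries, and 58 genes were listed at 0 in 1 library while both other replicates of its group stood at 5 TPM or more. These were kept, and the tests were repeated without each set, as alternatives chosen after seeing the data. Replicates were compared with Pearson's r on log2(TPM + 1), and principal components were computed on the centred log2 values of the tested genes.

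Groups were taken from the sample titles. Values were not rescaled between libraries. Genes with at least 1 TPM in at least 3 libraries were kept (12695), and log2(TPM + 1) was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over the 18 libraries and moderated variances (trend and robust options, 12 residual degrees of freedom and a median of 3.18 prior ones). The comparisons were each later group against Control and each step between neighbouring groups in order (9 in all, 2-sided moderated t tests), with an F test over the 6 group means. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and a gene was called at an adjusted p under 0.05. Means, SDs and SEs were computed over libraries, and SEs are those of the moderated fit. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

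Gene lists were written from general knowledge of adipogenesis and of dividing cells. The 26 lists hold 12 to 52 genes each and cover cell division, fat cell function, matrix, hormone and stress responses, clock, ribosome, housekeeping genes and markers of other cell types. For each list the genes called higher and lower were counted, with p-values adjusted over all genes and adjusted over the list alone, and the 23 lists with at least 5 measured genes were tested with camera in limma with the correlation between genes estimated for each list. P-values were adjusted over the lists of a comparison. The preset correlation of 0.01 and the rotation test fry were alternatives. The lists, the groups, the comparisons, the filter, the tests, the alternatives below and the rule for naming genes were fixed before the data were examined.

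Genes that could be named were set by rule. A panel of 24 genes could be named in any comparison, of which Ucp1 did not pass the filter. In each comparison the 4 called genes with the highest and the 4 with the lowest log2 fold change were named, if they had a mean of at least 10 TPM in the higher group and ranges that do not overlap. Names of predicted genes and of unnamed models (Gm, Rik, LOC, BC, AK, Mir and Snor) were left out. For each list described, up to 4 called members with the largest log2 fold change in size could be named, or, where 0 were called, up to 2 with the highest mean TPM. Chance alone gives ranges that do not overlap in 10% of genes with 3 against 3 libraries.

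The fit was tested on simulated data with the spread of these libraries, in which 200 of 12695 genes were changed in each comparison. With 3 libraries per group it called 89.4 to 97.0% of genes changed by 2 log2 units. The range was 70.1 to 89.6% for changes of 1 and 37.3 to 61.2% for 0.5. The real comparisons called 21.7 to 71.4% of genes. The adjusted threshold depends on that share, so these rates are not the power of the real tests. Between 3 and 13 unchanged genes were called per comparison.

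The alternatives were a pseudocount of 0.1, no filter (genes at 0 throughout left out), a filter of 5 TPM, median-ratio scaling and quantile normalization between libraries, a fit on the 6 libraries compared alone, the replicate number as a block, array weights, a log2 fold change of at least 1 as well (for the F test an adjusted p under 0.01), and leaving out each library in turn. Other splits of the libraries were counted (the 10 splits of each pair of groups, and 100 regroupings for the F test). Curated RefSeq transcripts were used to count transcripts per gene, and GENCODE transcripts to look for 50-base stretches shared between genes. They come from a later build than mm9, and no position was taken from them.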

Results

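Polyadenylated RNA was sequenced from mouse 3T3-L1 cells, a fibroblast line that turns into fat cells when given inducers. Confluent cells received insulin, dexamethasone and IBMX, a phosphodiesterase inhibitor that raises cAMP, for 48 h and insulin afterwards. The 18 libraries fell into 6 groups of 3: Control, MCE1 and MCE2, which are stages of the divisions that induced cells pass through before differentiating (mitotic clonal expansion), and Day4, Day6 and Day8. The labels give no hour for MCE1 or MCE2, do not say whether Control cells had stopped dividing, and do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples. Each value is a gene's TPM, which keeps no read depth, so the depth is unknown. The 3 libraries of each group are given as mean ± SD in TPM (n = 3), and positions are those of the mm9 build, counted from 1. Changes are on the log2(TPM + 1) scale, which understates changes of genes with few TPM, and a value ± SE in parentheses after a gene is its log2 fold change.

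Of 25209 gene names listed, 12695 reached 1 TPM in at least 3 of the 18 libraries and were tested. Across genes, Pearson's r between libraries was 0.976 to 0.991 within groups and 0.811 to 0.976 between groups, where genes are not independent replicates. The limma F test over the 6 group means called 11120 genes (87.6%) at an adjusted p under 0.05. Along the first principal component, which held 56.7% of the variance, the libraries ran in the order Control, MCE1, MCE2, Day4, Day6 and Day8. The second held 19.1% and set MCE1 and MCE2 apart from Control and Day8.

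**Figure D1:**
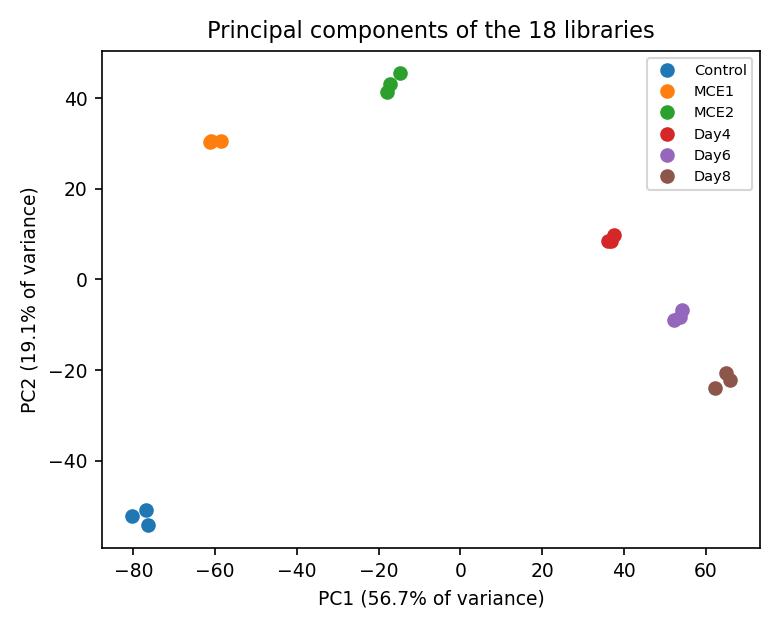
Scores of the 18 libraries on the first (56.7% of variance) and second (19.1%) principal components of log2(TPM + 1), 1 point per library, coloured by group. The 3 libraries of each group sit together, and MCE1 and MCE2 lie at the high end of the second component.

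The comparison of MCE1 with Control asks what had changed at the earlier stage of clonal expansion. The early adipogenic factors C/EBP beta and delta, glucocorticoid responsive genes and genes of the mature fat cell rose, while the genes of cholesterol synthesis fell. Of 12695 genes, 2799 were higher and 3727 lower at MCE1 (n = 3 per group), and 1723 of these changed by 1 or more on the log2 scale. Median-ratio scaling changed the balance to 3611 higher of 6673 called and quantile normalization to 3381 of 6541, so the excess of lower genes depends on the scaling. Cebpb (chromosome 2, 167514415 to 167515932) stood at 1021 ± 109 TPM against 244 ± 49.2 (log2 fold change 2.08, SE 0.16, adjusted p = 2.27e-08), and Cebpd (chromosome 16, 15887379 to 15889638) at 147 ± 1.53 against 23.2 ± 0.796 (log2 fold change 2.62, SE 0.07, adjusted p = 8.78e-14). Cebpa (chromosome 7, 35904312 to 35906947), which acts later in adipogenesis, rose from 3.57 ± 0.356 to 19.3 ± 1.85 TPM (log2 fold change 2.15, SE 0.16, adjusted p = 9.32e-09). Pparg (chromosome 6, 115310969 to 115440419), the nuclear receptor that drives fat cell formation, was not called here or in any other comparison. It was called higher at MCE2 than at MCE1 in a fit on the 6 libraries alone (1.16), and at Day6 than in Control without Day6 replicate 1 (1.53). Its 3 MCE1 libraries read 18.9, 8.87 and 26.5 TPM and those of Control 33, 29.5 and 32.1 TPM. In the list of adipogenic transcription factors 9 of 18 genes rose, 2 fell and 7 were not called (9 and 2 adjusted over the list alone), with camera adjusted p = 0.00109 with the preset correlation and adjusted p = 0.0537 with an estimated correlation. Quantile normalization called this list (adjusted p = 0.0277, median 0.53), as did a pseudocount of 0.1 (0.0338).

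Glucocorticoid responsive genes rose as a group in the cells given dexamethasone. In that list 17 of 19 genes rose and 2 fell (17 and 2 adjusted over the list alone), with a median log2 fold change of 2.24 and camera adjusted p = 0.00696. Fkbp5, an inhibitor of the glucocorticoid receptor, rose to 436 ± 7.21 from 50.9 ± 1.56 TPM (log2 fold change 3.07, SE 0.08, adjusted p = 6.6e-14). Glul rose by 3.46 ± 0.06 and Zbtb16 by 3.43 ± 0.16 log2 units (± SE). Lcn2 (chromosome 2, 32240157 to 32243259), a secreted iron and lipid carrier, had the highest log2 fold change of the genes named by rule, from 0.275 ± 0.249 to 801 ± 79.4 TPM (log2 fold change 9.31, SE 0.14, adjusted p = 1.17e-16). It was followed by Retnla (6.55, SE 0.27, 100.4 ± 1.21 TPM at MCE1). Next came Ear2 (6.25, SE 0.15, 76.1 ± 7.06 TPM), though Ear2 shares 41.5% of its 50-base stretches with other genes. S100a8 was listed at 0 in the 3 Control libraries and stood at 57.7 ± 1.30 TPM at MCE1. For genes of the mature fat cell 26 of 38 genes rose, 2 fell and 10 were not called (26 and 2 adjusted over the list alone). The median was 1.03, with camera adjusted p = 0.00696. Fabp4 (chromosome 3, 10204343 to 10208616), a fatty acid carrier, rose from 28 ± 2.23 to 184 ± 12 TPM (log2 fold change 2.67, SE 0.09, adjusted p = 5.49e-13), and Lpl (chromosome 8, 71404454 to 71430831), which frees fatty acids for uptake, from 101 ± 5.14 to 463 ± 44 (log2 fold change 2.18, SE 0.07, adjusted p = 4.73e-13). Plin1 (perilipin) and Adipoq (adiponectin) were listed at 0 in each Control library and read 2.13, 3.78 and 5.53 TPM and 0.620, 1.98 and 0.640 TPM at MCE1. For genes of mitochondrial oxidation 36 of 50 genes rose, 5 fell and 9 were not called (39 and 5 adjusted over the list alone). The median was 0.33, with camera adjusted p = 0.0312. Median-ratio scaling raised this to adjusted p = 0.194 (median 0.45) and quantile normalization to adjusted p = 0.136 (median 0.29). Pcx, which feeds the citrate cycle, rose by 3.04 ± 0.09.

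Of the genes of DNA replication and mitosis more rose than fell at MCE1, by small amounts. Among 51 replication genes 28 rose, 4 fell and 19 were not called (28 and 4 adjusted over the list alone). The median was 0.30 (camera adjusted p = 7.93e-05 with the preset correlation and adjusted p = 0.0681 with an estimated correlation). Pcna (chromosome 2, 132075022 to 132078916), the sliding clamp of DNA polymerases, stood at 827 ± 20.1 TPM against 547 ± 24.1 (log2 fold change 0.60, SE 0.05, adjusted p = 2.57e-08). Rrm2, which supplies nucleotides, rose by 0.93 ± 0.07. Mcm2, Mcm5 and Rif1, which act at replication origins, were not called (0.05, 0.21 and 0.19, adjusted p = 0.477, 0.221 and 0.246), though median-ratio scaling called the 3 higher (0.17, 0.33 and 0.30) and quantile normalization called Rif1 higher (0.28). Among 48 mitosis genes 24 rose, 5 fell and 19 were not called (24 and 5 adjusted over the list alone). The median was 0.26 (camera adjusted p = 0.00109 with the preset correlation and adjusted p = 0.303 with an estimated correlation). Top2a (chromosome 11, 98854261 to 98885503), a topoisomerase of dividing cells, rose from 243 ± 9.49 to 572 ± 26.5 TPM (log2 fold change 1.23, SE 0.06, adjusted p = 1.14e-10). Ccnb1 rose by 0.28 ± 0.08, and Mki67 was not called (0.09, adjusted p = 0.623). The cyclin Ccnd1 (chromosome 7, 152115836 to 152125830) fell from 579 ± 21.8 to 206 ± 3.75 TPM (log2 fold change -1.48, SE 0.09, adjusted p = 1.4e-09), and the kinase inhibitor Cdkn2b (-1.80 ± 0.08). Cdkn1a fell by 2.55 (adjusted p = 0.0199), with libraries of 4.13, 0 and 4.46 TPM that lay far apart, a call that ended without Control replicate 1 (-2.38), without MCE1 replicate 2 (-1.75) and with a pseudocount of 0.1 (-3.76). Myc, a driver of growth, rose by 0.66 ± 0.27 (adjusted p = 0.0489), a call that ended without any 1 of Control replicates 1, 2 and 3 and MCE1 replicates 1 and 2 (0.54 to 0.70), with a pseudocount of 0.1 and with no filter. In the mixed list of cell cycle regulators 8 of 23 genes fell, 7 rose and 8 were not called (8 and 8 adjusted over the list alone), with camera adjusted p = 0.938.

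Acta2 (chromosome 19, 34314826 to 34329863), the smooth muscle actin of activated fibroblasts, fell from 996 ± 71.3 to 6.94 ± 1.03 TPM (log2 fold change -6.98, SE 0.15, adjusted p = 9.12e-15), the lowest log2 fold change named by rule at MCE1. Myl9 (-6.25 ± 0.23), Actg2 (-5.48 ± 0.14) and Tnnt2 (-5.38 ± 0.18) fell too. In the list of fibroblast matrix and contractile genes 24 of 38 genes fell, 10 rose and 4 were not called (25 and 11 adjusted over the list alone). The median was -0.70 (camera adjusted p = 0.00399 with the preset correlation and adjusted p = 0.234 with an estimated correlation). Median-ratio scaling called this list lower (adjusted p = 0.0481, median -0.59). Col1a1 fell from 1235 ± 68.9 to 616 ± 27.4 TPM (SE 0.14 log2 units, adjusted p = 2.24e-05). For genes of the basement membrane, the sheet of matrix around fat cells, 12 of 16 genes rose, 2 fell and 2 were not called (12 and 2 adjusted over the list alone). The median was 1.48 (camera adjusted p = 3.56e-07 with the preset correlation and adjusted p = 0.257 with an estimated correlation). Col4a1 rose from 481 ± 24 to 2450.3 ± 167 TPM and Col6a2 from 403 ± 46.3 to 2054 ± 73.5, by 2.35 ± 0.10 and 2.35 ± 0.07. For cholesterol synthesis 21 of 22 genes fell and 1 rose (21 and 1 adjusted over the list alone). The median was -0.81, with camera adjusted p = 0.0283. Msmo1 (-1.80 ± 0.04) and Fdft1 (-1.62 ± 0.05) had the lowest values of the list. Of 14 macrophage markers 4 passed the filter, and 3 of these fell (Lyz2 2.37 ± 0.810 TPM in Control and 0.388 ± 0.398 at MCE1).

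Comparing MCE2 with Control shows the later stage of clonal expansion. Replication and mitosis genes lay below Control, and the genes of the fat cell stood far above it. Of the tested genes 2969 were higher and 4964 lower (n = 3 per group), 2595 of them by 1 or more on the log2 scale. The median of all genes was -0.17, and median-ratio scaling and quantile normalization moved it up by 0.17 each and gave 3932 higher of 7858 and 3831 higher of 7751, so list medians below are also given relative to all genes. For mature fat cell genes 30 of 38 genes rose, 2 fell and 6 were not called (30 and 2 adjusted over the list alone). The median was 3.59 (3.76 relative to all genes), with camera adjusted p = 0.00046. Fabp4 reached 1457 ± 162 TPM (log2 fold change 5.65, SE 0.09, adjusted p = 6.03e-17), Lpl 1708 ± 90.6 (log2 fold change 4.07, SE 0.07, adjusted p = 1.64e-16) and Cidec, a lipid droplet protein, 149 ± 24.9 (7.10, SE 0.16). Gpd1, which makes the glycerol backbone of triglycerides, rose from 0.556 ± 0.0702 to 207 ± 1.54 TPM (log2 fold change 7.07, SE 0.08, adjusted p = 4.9e-18). Retn (resistin), G0s2, Plin1 and Adipoq, listed at 0 in each Control library, stood at 177 ± 17.4, 124 ± 3.08, 71.3 ± 12.4 and 60.6 ± 2.60 TPM. Cebpa rose to 113 ± 17.2 TPM (log2 fold change 4.64, SE 0.16, adjusted p = 5.29e-13), while Cebpb at 1076 ± 71.2 and Cebpd at 210.0 ± 13.4 TPM were above Control by 2.15 ± 0.16 and 3.12 ± 0.07. Among adipogenic transcription factors 13 of 18 genes rose, 4 fell and 1 was not called (13 and 4 adjusted over the list alone). The median was 1.62, with camera adjusted p = 0.0161.

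For DNA replication 47 of 51 genes fell, 0 rose and 4 were not called (48 and 0 adjusted over the list alone) at MCE2. The median was -0.90 (-0.73 relative to all genes), with camera adjusted p = 0.00763. Pcna fell to 311 ± 12.6 TPM (log2 fold change -0.81, SE 0.05, adjusted p = 3.79e-10) and Mcm2 (chromosome 6, 88833468 to 88848774) from 189.6 ± 4.09 to 101 ± 4.72 (log2 fold change -0.90, SE 0.05, adjusted p = 2.97e-10), as did Mcm5 (-0.74 ± 0.14), Rif1 (-0.96 ± 0.13) and Pola1 (-2.03 ± 0.11). Of the mitosis genes 45 fell and 0 rose (45 and 0 adjusted over the list alone). The median was -1.25 (-1.08 relative to all genes), with camera adjusted p = 0.0242. Mki67 fell from 124 ± 2.74 to 28.4 ± 4.37 TPM (log2 fold change -2.09, SE 0.14, adjusted p = 1.71e-09), as did Kif23 (-2.72 ± 0.10) and Ccnb1 (-0.80 ± 0.08). Top2a was not called (0.00, 243 ± 19.1 TPM), though median-ratio scaling called it higher by 0.20 (adjusted p = 0.00227). Ccnd1 fell to 79.7 ± 2.98 TPM (log2 fold change -2.85, SE 0.09, adjusted p = 3.22e-13), as did Cdkn1a (-2.24 ± 0.85), with libraries of 4.31, 9.0 and 0 TPM, while Myc rose from 40.9 ± 2.83 to 109 ± 9.47 TPM (log2 fold change 1.39, SE 0.27, adjusted p = 0.000277). The call of Cdkn1a ended without Control replicate 1, 2 or 3 (-2.35 to -2.07), without MCE2 replicate 3 (-1.29), with a pseudocount of 0.1 (-3.41) and under quantile normalization (-1.97). For cell cycle regulators as a list, 16 fell, 2 rose and 5 were not called (16 and 2 adjusted over the list alone, camera adjusted p = 0.0148 with the preset correlation and adjusted p = 0.238 with an estimated correlation).

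Glucocorticoid responsive genes stayed above Control at MCE2, where 17 of 19 genes rose, 1 fell and 1 was not called (17 and 1 adjusted over the list alone). The median was 2.43, with camera adjusted p = 0.00409. Fkbp5 stood at 611 ± 22 TPM (log2 fold change 3.56, SE 0.08, adjusted p = 4.57e-15) and Lcn2 at 561 ± 19.6 (8.80, SE 0.14). For mitochondrial oxidation 46 of 50 genes rose, 2 fell and 2 were not called (46 and 2 adjusted over the list alone). The median was 0.72 (0.89 relative to all genes), with camera adjusted p = 0.00269, which median-ratio scaling raised to adjusted p = 0.0662 with a median of 0.92. Pcx rose by 4.71 ± 0.09 and Acadm, of fatty acid oxidation, by 1.75 ± 0.06. For the synthesis of fatty acids and triglycerides 16 of 24 genes rose, 6 fell and 2 were not called (16 and 7 adjusted over the list alone, camera adjusted p = 1.27e-05 with the preset correlation and adjusted p = 0.259 with an estimated correlation). Dgat2 rose from 5.63 ± 0.176 to 160.0 ± 2.41 TPM, Scd1 by 2.37 ± 0.09 and Fasn by 0.83 ± 0.13. Acta2 (-7.23 ± 0.15), Myl9 (-6.28 ± 0.23) and Col1a1 (-1.59 ± 0.14) were lower, and Grem1, a BMP inhibitor, fell from 525 ± 47.7 to 7.11 ± 1.07 TPM (log2 fold change -6.02, SE 0.12, adjusted p = 7.04e-16). The chemokine Ccl2 fell from 436 ± 56.2 to 5.56 ± 0.654 TPM (log2 fold change -6.05, SE 0.13, adjusted p = 2.34e-15). For fibroblast matrix and contractile genes 27 of 38 genes fell, 9 rose and 2 were not called (27 and 9 adjusted over the list alone). The median was -1.27 (camera adjusted p = 0.00191 with the preset correlation and adjusted p = 0.214 with an estimated correlation). Median-ratio scaling called this list lower (adjusted p = 0.0188, median -1.07). Of the 4 macrophage markers measured 3 fell at MCE2, Lyz2 being listed at 0 in its 3 libraries.

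The step from MCE1 to MCE2 was tested directly, since it separates the stages of clonal expansion. Replication and mitosis genes fell, and mature fat cell genes rose. Of the tested genes 2242 rose and 3197 fell (n = 3 per group), with 970 changing by 1 or more. Median-ratio scaling gave 2758 higher of 5464 called and quantile normalization 2754 of 5386, so the excess of lower genes depends on the scaling. For DNA replication 50 of 51 genes fell, 0 rose and 1 was not called (50 and 0 adjusted over the list alone). The median was -1.22, with camera adjusted p = 0.000171. Pcna fell from 827 ± 20.1 to 311 ± 12.6 TPM (log2 fold change -1.41, SE 0.05, adjusted p = 3.86e-12), Mcm2 from 196 ± 5.31 to 101 ± 4.72 (log2 fold change -0.95, SE 0.05, adjusted p = 7.05e-10) and Rif1 (chromosome 2, 51928357 to 51982288), which sets the timing of replication origins, from 25.4 ± 1.89 to 11 ± 1.94 (log2 fold change -1.15, SE 0.13, adjusted p = 2.41e-06). Prim1 (-2.18 ± 0.10) and Pola1 (-2.03 ± 0.11), which start DNA strands, and Mcm5 (-0.94 ± 0.14) fell too. For mitosis 47 of 48 genes fell, 0 rose and 1 was not called (47 and 0 adjusted over the list alone). The median was -1.63, with camera adjusted p = 0.00149. Mki67 fell from 132 ± 7.36 to 28.4 ± 4.37 TPM (log2 fold change -2.18, SE 0.14, adjusted p = 3.63e-09), as did Top2a (-1.23 ± 0.06) and Ccnb1 (-1.08 ± 0.08). In the cell cycle regulators 16 of 23 genes fell, 2 rose and 5 were not called (16 and 2 adjusted over the list alone, camera adjusted p = 0.000415 with the preset correlation and adjusted p = 0.0736 with an estimated correlation). Median-ratio scaling (adjusted p = 0.0234) and quantile normalization (0.0155) called this list lower. Ccnd1 (-1.36 ± 0.09), Rbl1 (-1.97 ± 0.11) and E2f8 (-1.97 ± 0.21) were among the genes that fell.

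Fat cell genes rose over the same step, as 30 of 38 genes rose, 0 fell and 8 were not called (30 and 0 adjusted over the list alone). The median was 1.81, with camera adjusted p = 0.000121. Gpd1 rose from 3.68 ± 0.474 to 207 ± 1.54 TPM (log2 fold change 5.48, SE 0.08, adjusted p = 4.57e-16) and G0s2 from 2.97 ± 0.644 to 124 ± 3.08 (log2 fold change 4.99, SE 0.10, adjusted p = 6.71e-15). Adipoq (chromosome 16, 23146609 to 23158041) rose by 4.95 ± 0.16 and Cfd, the secreted protease adipsin, by 4.31 ± 0.12. Cebpa rose by 2.49 ± 0.16 and Cebpd by 0.51 ± 0.07. Cebpb was not called (0.08, adjusted p = 0.749). For adipogenic transcription factors 11 rose, 4 fell and 3 were not called (11 and 4 adjusted over the list alone, camera adjusted p = 0.00333 with the preset correlation and adjusted p = 0.0736 with an estimated correlation). Quantile normalization called it higher (adjusted p = 0.0475). For mitochondrial oxidation 39 of 50 genes rose, 1 fell and 10 were not called (39 and 1 adjusted over the list alone). The median was 0.39, with camera adjusted p = 0.00149, which median-ratio scaling raised to adjusted p = 0.0629 with a median of 0.47. In fatty acid and triglyceride synthesis 17 of 24 genes rose, 2 fell and 5 were not called (17 and 2 adjusted over the list alone, camera adjusted p = 1.2e-10 with the preset correlation and adjusted p = 0.0857 with an estimated correlation). Median-ratio scaling called it higher (adjusted p = 0.0419). Dgat2 rose by 3.78 ± 0.07 and Fasn by 0.70 ± 0.13. For cholesterol synthesis 11 of 22 genes rose, 3 fell and 8 were not called (11 and 3 adjusted over the list alone, camera adjusted p = 0.000224 with the preset correlation and adjusted p = 0.1 with an estimated correlation). Insig1 rose by 0.95 ± 0.06. In the glucocorticoid responsive list 10 of 19 genes rose, 3 fell and 6 were not called (10 and 4 adjusted over the list alone, camera adjusted p = 0.00497 with the preset correlation and adjusted p = 0.181 with an estimated correlation). Fkbp5 rose by 0.49 ± 0.08. The lowest log2 fold changes were those of Sprr2k (-4.98 ± 0.25), Sprr1a (-3.55 ± 0.32), Cxcl5 (-3.43 ± 0.20) and Ccl2 (-3.33 ± 0.13). Col1a1 fell by 0.59, Wnt5a, which opposes adipogenesis, fell by 1.86, and Myc rose by 0.73 ± 0.27 (adjusted p = 0.037), a call that ended without MCE1 replicate 3 (0.50), without MCE2 replicate 1, 2 or 3 (0.69 to 0.80) and with no filter (0.73).

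**Figure D2:**
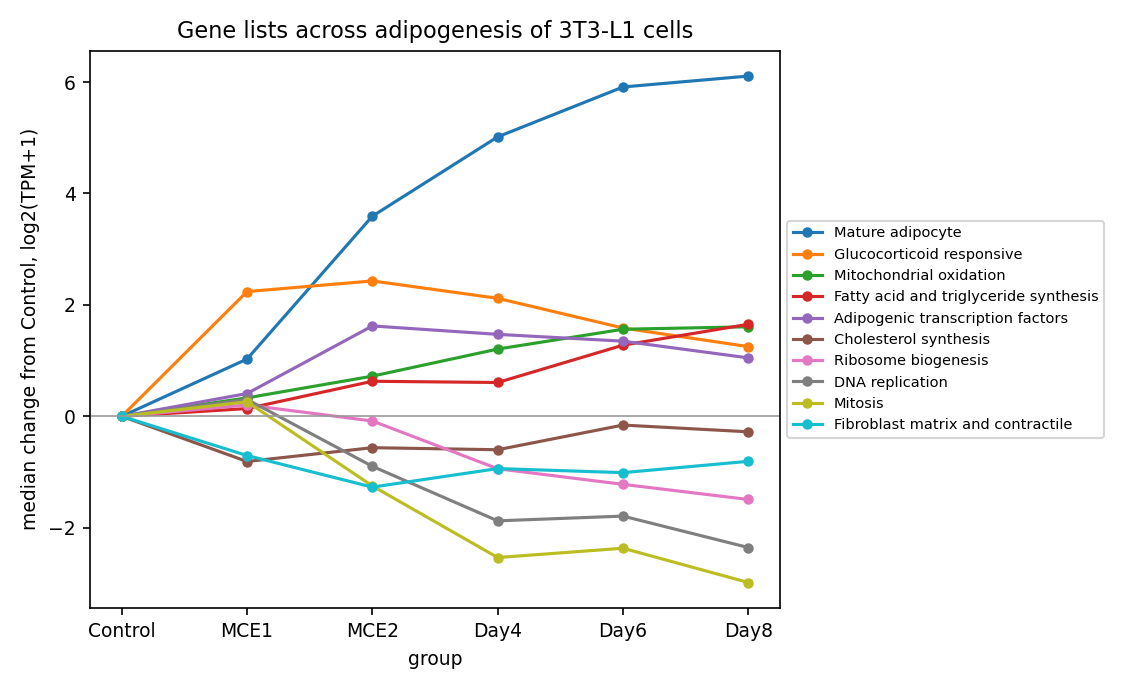
Median log2 change from Control (log2 units of TPM + 1, vertical axis) of the measured genes of 10 lists at the 6 groups in order, 1 line per list. The medians of DNA replication and mitosis are 0.30 and 0.26 at MCE1, -0.90 and -1.25 at MCE2 and -2.36 and -2.98 at Day8, while the mature adipocyte median is 1.03, 3.59 and 6.11.

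Day4 (day 4 after differentiation stimuli, start or end not given) was compared with Control. Glucocorticoid responsive genes had not fallen as a list from MCE2 (median -0.13, camera adjusted p = 0.89). Fat cell genes stood far above Control, Fabp4 alone holding 1.28 to 1.36% of the listed TPM, and replication and mitosis genes were lower. Of the tested genes 3771 were higher and 4985 lower (n = 3 per group), 3469 of them by 1 or more. The median of all genes was -0.11, and median-ratio scaling moved it by 0.13 and gave 4452 higher of 8701 called. Quantile normalization gave 4169 of 8702, so the excess of lower genes was lost with the former alone. For mature fat cell genes 35 of 38 genes rose, 0 fell and 3 were not called (35 and 1 adjusted over the list alone). The median was 5.02 (5.13 relative to all genes), with camera adjusted p = 0.000278. Fabp4 stood at 11665 ± 397 TPM (log2 fold change 8.66, SE 0.09, adjusted p = 2.14e-19), Lpl at 3294 ± 145 (log2 fold change 5.02, SE 0.07, adjusted p = 9.76e-18), Cidec at 1346 ± 141 (10.27, SE 0.16) and Cebpa at 182 ± 19 (log2 fold change 5.32, SE 0.16, adjusted p = 7.05e-14). Adipoq, Retn, Cfd and Plin1, listed at 0 in each Control library, stood at 1364 ± 57.6, 851 ± 26.7, 759 ± 37.3 and 228 ± 14.3 TPM. The lipogenic factor Thrsp rose from 0.0513 ± 0.0888 to 647 ± 22.8 TPM (log2 fold change 9.27, SE 0.07, adjusted p = 3.62e-20), and Scd1, a fatty acid desaturase, by 3.43 ± 0.09. In the list of fatty acid and triglyceride synthesis 16 of 24 genes rose, 6 fell and 2 were not called (16 and 6 adjusted over the list alone, camera adjusted p = 5.8e-05 with the preset correlation and adjusted p = 0.234 with an estimated correlation). For adipogenic transcription factors 13 rose, 3 fell and 2 were not called (13 and 3 adjusted over the list alone), with camera adjusted p = 0.0278. Nr1h3 rose by 3.90 ± 0.28.

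Replication genes fell further against Control by Day4, as 48 of 51 genes fell, 0 rose and 3 were not called (48 and 0 adjusted over the list alone). The median was -1.88 (-1.77 relative to all genes), with camera adjusted p = 0.00104. Mcm2 fell to 37.4 ± 0.954 TPM (log2 fold change -2.31, SE 0.05, adjusted p = 2.72e-15) and Pcna to 163 ± 6.67 (log2 fold change -1.74, SE 0.05, adjusted p = 2.62e-14), as did Mcm5 (-2.46 ± 0.14) and Rif1 (-1.44 ± 0.13). For mitosis 47 of 48 genes fell, 0 rose and 1 was not called (47 and 0 adjusted over the list alone). The median was -2.54 (-2.43 relative to all genes), with camera adjusted p = 0.00496. Mki67 fell to 8.90 ± 1.21 TPM (log2 fold change -3.66, SE 0.14, adjusted p = 1.23e-12), as did Top2a (-2.52 ± 0.06), Ccnb1 (-2.54 ± 0.08), Kif23 (-4.17 ± 0.10) and Ccnd1 (-3.33 ± 0.09). For ribosome biogenesis 26 of 29 genes fell, 0 rose and 3 were not called (26 and 0 adjusted over the list alone). The median was -0.94 (camera adjusted p = 6.85e-08 with the preset correlation and adjusted p = 0.0537 with an estimated correlation). Quantile normalization called this list lower (adjusted p = 0.0336). Mitochondrial oxidation genes rose, as 47 of 50 genes rose, 1 fell and 2 were not called (47 and 1 adjusted over the list alone). The median was 1.21 (1.32 relative to all genes), with camera adjusted p = 0.00104, which median-ratio scaling raised to adjusted p = 0.0532 with a median of 1.35. Pcx rose by 4.81 ± 0.09 and Acadm from 52.5 ± 2.92 to 586 ± 6.10 TPM (log2 fold change 3.46, SE 0.06, adjusted p = 2.73e-16). In the glucocorticoid responsive list 19 of 19 genes rose and 0 fell (19 and 0 adjusted over the list alone), with camera adjusted p = 0.00325, and Fkbp5 stood at 557 ± 17.6 TPM (log2 fold change 3.43, SE 0.08, adjusted p = 5.6e-15). Of the brown and beige list 8 of 20 genes passed the filter, without Ucp1. Of these 5 were higher and 0 lower (camera adjusted p = 0.00455 with the preset correlation and 0.0537 with an estimated one).

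Hmga2 (chromosome 10, 119798324 to 119913525), a chromatin protein of immature cells, fell from 840.2 ± 45.6 to 10.8 ± 3.85 TPM (log2 fold change -6.21, SE 0.26, adjusted p = 6.12e-12) as did the peptide hormone Cck (-6.17 ± 0.23), Acta2 (-7.46 ± 0.15) and the transcript U90926 (-5.99 ± 0.12). Dlk1, a preadipocyte protein, fell by 2.17 (adjusted p = 0.0182), with libraries of 0, 9.09 and 10.5 TPM and 11.7, 30.4 and 25.8 TPM in Control that lay far apart. That call ended without Control replicate 2 (-1.92) or 3 (-2.03), without Day4 replicate 1 (-1.03) and in a fit on the 6 libraries alone (-2.17). In the other comparisons it was not called, though it was called lower from MCE2 to Day4 without Day4 replicate 3 (-2.07) and at Day6 against Control in a fit on the 6 libraries alone (-0.89). For preadipocyte and anti-adipogenic genes 10 fell, 2 rose and 4 were not called (10 and 2 adjusted over the list alone, camera adjusted p = 0.0252 with the preset correlation and adjusted p = 0.215 with an estimated correlation), Inhba (-4.01 ± 0.12) among the lower ones. For fibroblast matrix and contractile genes 25 fell, 10 rose and 3 were not called (25 and 10 adjusted over the list alone, camera adjusted p = 0.0138 with the preset correlation and adjusted p = 0.234 with an estimated correlation), and Col1a1 was not called (0.24, adjusted p = 0.14), though median-ratio scaling (0.39), array weights (0.26) and a fit on the 6 libraries alone (0.24) called it higher. Of the basement membrane genes 12 rose, 3 fell and 1 was not called (12 and 3 adjusted over the list alone, camera adjusted p = 8.78e-05 with the preset correlation and adjusted p = 0.317 with an estimated correlation). Nid2 rose by 3.19 ± 0.10. The 4 measured macrophage markers fell, and the 4 measured epithelial markers rose, at low values. Krt18 and Krt8 were listed at 0 in each Control library and read 1.26, 2.59 and 1.17 TPM and 0.920, 1.47 and 1.10 TPM at Day4.

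The step from MCE2 to Day4 covers the passage from clonal expansion to differentiated cells. Fat cell genes rose, and genes of replication, mitosis and ribosome biogenesis fell. Of the tested genes 3759 rose and 2791 fell (n = 3 per group), 1384 of them by 1 or more. Quantile normalization gave 3110 higher of 6502 called and median-ratio scaling 3480 of 6706, so the excess of higher genes was lost under the former and smaller with the latter. For mature fat cell genes 32 of 38 genes rose, 3 fell and 3 were not called (32 and 3 adjusted over the list alone). The median was 1.64, with camera adjusted p = 0.002. Adipoq rose from 60.6 ± 2.60 to 1364 ± 57.6 TPM (log2 fold change 4.47, SE 0.16, adjusted p = 7.7e-12) and Fabp4 from 1457 ± 162 to 11665 ± 397 (log2 fold change 3.01, SE 0.09, adjusted p = 6.58e-13). Cfd rose by 3.63 ± 0.12 and Plin1 (chromosome 7, 86866050 to 86877662) by 1.68 ± 0.19. Cebpa rose by 0.69 ± 0.16 while Cebpb fell from 1076 ± 71.2 to 558 ± 96.8 TPM (log2 fold change -0.96, SE 0.16, adjusted p = 0.000123), and Klf15, a factor induced in fat cells, rose by 3.14 ± 0.15. For replication 42 of 51 genes fell, 0 rose and 9 were not called (43 and 0 adjusted over the list alone). The median was -0.93, with camera adjusted p = 0.00152. The genes that fell included Mcm2 (-1.41 ± 0.05), Mcm5 (-1.73 ± 0.14) and Pcna (-0.93 ± 0.05). For mitosis 46 of 48 genes fell, 0 rose and 2 were not called (47 and 0 adjusted over the list alone). The median was -1.22, with camera adjusted p = 0.00228. Top2a fell from 243 ± 19.1 to 41.4 ± 0.984 TPM (log2 fold change -2.52, SE 0.06, adjusted p = 1.35e-13), as did Mki67 (-1.57 ± 0.14).

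Ribosome biogenesis genes fell over this step. Of 29 genes 28 fell, 0 rose and 1 was not called (28 and 0 adjusted over the list alone). The median was -0.73, with camera adjusted p = 0.00879. Of the list, Nolc1 (-1.45 ± 0.09) and Polr1b (-1.39 ± 0.09) fell. Myc fell from 109 ± 9.47 to 31.4 ± 9.05 TPM (log2 fold change -1.80, SE 0.27, adjusted p = 3.74e-05). At MCE2 Myc stood above Control by 1.39 while the list median was -0.08, and a link was not tested. The kinase inhibitor Cdkn2b rose from 32.1 ± 1.34 to 113 ± 4.45 TPM (log2 fold change 1.78, SE 0.08, adjusted p = 1.2e-10). Cdkn2a rose by 1.04 ± 0.11. For mitochondrial oxidation 39 of 50 genes rose, 3 fell and 8 were not called (41 and 3 adjusted over the list alone). The median was 0.48, with camera adjusted p = 0.0092, which median-ratio scaling raised to adjusted p = 0.22 with a median of 0.43. Ogn rose from 1.54 ± 0.477 to 98.2 ± 4.81 TPM (log2 fold change 5.31, SE 0.13, adjusted p = 1.35e-13), Itgbl1 by 5.16 ± 0.16 and Ubd by 4.97 ± 0.13. Col1a1 rose from 410.3 ± 23.2 to 1462 ± 71.6 TPM (log2 fold change 1.83, SE 0.14, adjusted p = 4.2e-08). The lowest log2 fold changes named by rule were those of Krt15 (-4.48 ± 0.32), Hist1h2ao (-4.09 ± 0.73), Krt13 (-3.79 ± 0.20) and Cryge (-3.54 ± 0.28). The mitochondrial chaperone Hspd1 rose by 5.41 ± 1.14, with MCE2 libraries of 27.9, 36.3 and 6.34 TPM. Hspd1 and Hist1h2ao are among 97 genes whose replicates lay far apart in at least 1 group.

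Day6 and Day8 were each compared with Control to follow maturation. Fat cell, mitochondrial and most measured brown and beige genes stood above Control at both days, and replication, mitosis and ribosome biogenesis genes below it. At Day6 3837 genes were higher and 5006 lower, and at Day8 4025 were higher and 5036 lower (n = 3 per group), 3747 and 4109 of them by 1 or more. The medians of all genes were -0.12 and -0.10, and median-ratio scaling moved them by 0.13 and 0.11. It gave 4513 higher of 8814 called at Day6 and 4606 of 9076 at Day8, while quantile normalization gave 4088 of 8872 and 4290 of 9146. The excess of lower genes was thus lost with the former alone. At both days 37 of 38 mature fat cell genes rose and 1 was not called (37 and 0 adjusted over the list alone). At Day6 the median was 5.91 (6.03 relative to all genes), with camera adjusted p = 0.000164. At Day8 it was 6.11 (6.22 relative to all genes), with camera adjusted p = 0.00018. Fabp4 stood at 19239 ± 1202 TPM at Day6 (log2 fold change 9.38, SE 0.09, adjusted p = 8.51e-20) and 15628 ± 1352 at Day8 (log2 fold change 9.08, SE 0.09, adjusted p = 1.3e-19). Lpl stood at 5702 ± 249 and 5729 ± 338 (5.81 and 5.81). Adipoq, Cfd, Retn and G0s2, listed at 0 in each Control library, stood at 3594 ± 65.9, 2991 ± 334, 1249 ± 134 and 1813 ± 103 TPM at Day8. At Day6 the highest log2 fold changes named by rule were those of Adipoq (11.63 ± 0.16), Cfd (10.99 ± 0.12), Retn (10.72 ± 0.11) and Cidec (10.42 ± 0.16), and the lowest those of Hmga2 (-6.40 ± 0.26), Cck (-6.30 ± 0.23), Grem1 (-6.23 ± 0.12) and U90926 (-5.99 ± 0.12). Cebpa rose to 405 ± 96.8 TPM at Day8 (log2 fold change 6.45, SE 0.16, adjusted p = 5.09e-15). For adipogenic transcription factors 14 rose, 3 fell and 1 was not called at both days (14 and 3 adjusted over the list alone). Camera gave adjusted p = 0.0249 at Day6 and 0.0369 at Day8.

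**Figure D3:**
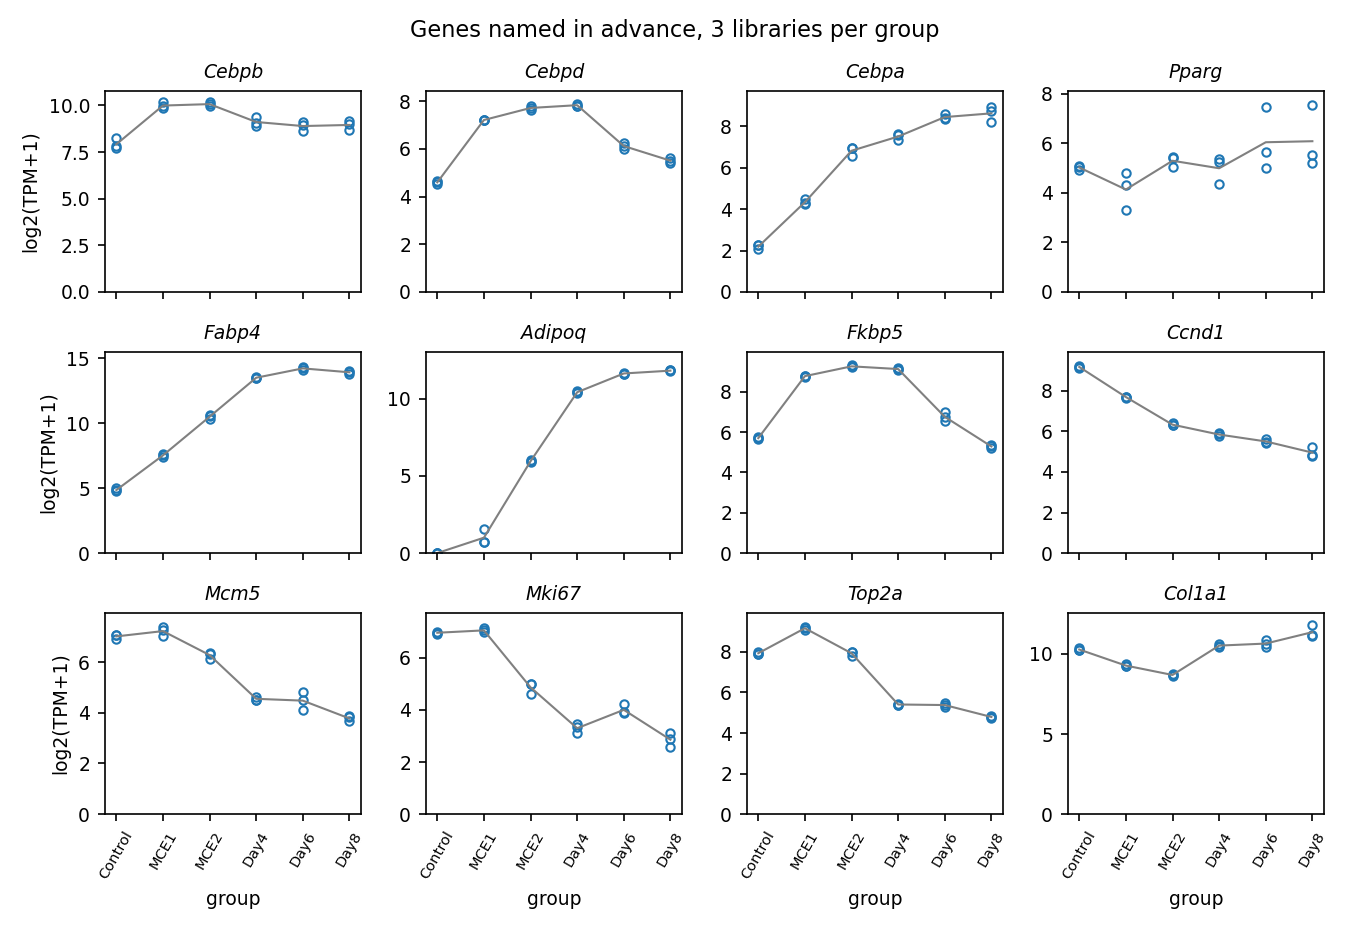
Values of 12 panel genes, as log2(TPM + 1), in each of the 18 libraries (points), with a line through the mean of each group of 3, by group in order. Mean Cebpa is 3.57 TPM in Control and 405 TPM at Day8, and mean Mcm5 is 128 and 12.7 TPM.

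For mitochondrial oxidation 48 of 50 genes rose and 2 fell (48 and 2 adjusted over the list alone) at Day8. The median was 1.61 (1.72 relative to all genes), with camera adjusted p = 0.00107. At Day6 48 rose, 1 fell and 1 was not called (49 and 1 adjusted over the list alone), with camera adjusted p = 0.000939. Cox7a1, a subunit found in heart and brown fat, rose from 0.688 ± 0.607 to 243 ± 25.7 TPM (log2 fold change 7.24, SE 0.35, adjusted p = 2.18e-11). Acadvl rose by 2.89 ± 0.06. Of the 8 measured brown and beige genes 7 rose and 1 fell (7 and 1 adjusted over the list alone) at Day6 (camera adjusted p = 0.0222). At Day8 7 rose, 0 fell and 1 was not called (7 and 0 adjusted over the list alone, camera adjusted p = 0.0212). Cox8b, listed at 0 in each Control library, stood at 109.7 ± 14.2 and 186 ± 40.4 TPM. Cox7a1 is in both lists. Ucp1, the uncoupling protein of brown fat, and most of the 20 listed genes did not pass the filter, so no thermogenic programme is shown. For fatty acid and triglyceride synthesis 20 rose, 1 fell and 3 were not called (20 and 1 adjusted over the list alone) at Day8 (camera adjusted p = 8.55e-09 with the preset correlation and adjusted p = 0.107 with an estimated correlation). At Day6 17 rose, 2 fell and 5 were not called (17 and 2 adjusted over the list alone, camera adjusted p = 4.82e-08 with the preset correlation and adjusted p = 0.133 with an estimated correlation). Median-ratio scaling called it higher at both days (adjusted p = 0.0392 at Day8 and 0.0498 at Day6). Scd1 rose from 97 ± 4.35 to 5799 ± 644 TPM at Day8 (log2 fold change 5.88, SE 0.09, adjusted p = 2.86e-17) and Fasn from 169 ± 8.06 to 416 ± 58.8 (log2 fold change 1.29, SE 0.13, adjusted p = 1.57e-07). For glucocorticoid responsive genes 18 rose and 1 fell (18 and 1 adjusted over the list alone) at Day6 (median 1.59, camera adjusted p = 0.00974). At Day8 16 rose and 3 fell (16 and 3 adjusted over the list alone, median 1.25, camera adjusted p = 0.0332). Fkbp5 stood at 38 ± 2.37 TPM at Day8, below Control (log2 fold change -0.41, SE 0.08, adjusted p = 0.000256).

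Replication genes fell against Control at both days, as 50 fell, 0 rose and 1 was not called (50 and 0 adjusted over the list alone) at Day6 (median -1.79, -1.67 relative to all genes, camera adjusted p = 0.00148). At Day8 49 fell, 0 rose and 2 were not called (49 and 0 adjusted over the list alone, median -2.36, -2.26 relative to all genes, camera adjusted p = 0.00107). Mcm5 fell from 128 ± 6.70 to 12.7 ± 0.975 TPM at Day8 (log2 fold change -3.23, SE 0.14, adjusted p = 3.66e-12), as did Mcm2 (-2.55 ± 0.05), Pcna (-2.39 ± 0.05) and Rif1 (-0.84 ± 0.13). Of the mitosis genes 47 fell and 0 rose at either day (47 and 0 adjusted over the list alone at both), with medians of -2.37 and -2.98 (camera adjusted p = 0.00931 and 0.00662). Mki67 stood at 15.1 ± 2.13 TPM at Day6 and 6.33 ± 1.29 at Day8 (log2 fold change -4.10, SE 0.14, adjusted p = 2.15e-13). Ccnd1 fell by 3.67 at Day6 and fell by 4.23 at Day8 against Control, and Myc fell by 1.36 at Day8. At Day6 Myc was not called, though it was called lower with array weights (-0.66) and without Day6 replicate 2 (-0.72). The 29 ribosome biogenesis genes fell at both days (29 and 0 adjusted over the list alone at both), with medians of -1.22 and -1.49 (camera adjusted p = 0.0249 and 0.0212). Col1a1 rose to 2681 ± 771 TPM at Day8 (log2 fold change 1.08, SE 0.14, adjusted p = 4.85e-06), and the proteoglycan Lum from 0.120 ± 0.112 to 125 ± 6.72 (log2 fold change 6.81, SE 0.12, adjusted p = 1.06e-16). Hmga2 (-6.83 ± 0.26), Cck (-6.30 ± 0.23), Grem1 (-6.20 ± 0.12), U90926 (-5.99 ± 0.12) and Acta2 (-5.92 ± 0.15) were lower at Day8. Cdkn1a fell by 3.95 at Day8, and its Day6 libraries read 0, 3.26 and 0 TPM. For basement membrane genes 13 rose and 3 fell (13 and 3 adjusted over the list alone) at Day8 (camera adjusted p = 1.22e-05 with the preset correlation and adjusted p = 0.253 with an estimated correlation). Col15a1 rose by 5.27 ± 0.10. Of the macrophage markers 3 fell at each day and 1 was not called, and of the epithelial ones 4 rose, Krt18 standing at 7.68 ± 0.776 TPM at Day8.

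Between Day4 and Day6, mature fat cell, brown and beige and cholesterol synthesis genes rose, and glucocorticoid responsive genes fell. Of the tested genes 1835 rose and 1422 fell (n = 3 per group), 368 of them by 1 or more. Quantile normalization gave 1755 higher of 3562 called and median-ratio scaling 1991 of 3390, so the excess of higher genes was lost under the former alone. For mature fat cell genes 26 of 38 genes rose, 1 fell and 11 were not called (28 and 1 adjusted over the list alone). The median was 0.70, with camera adjusted p = 0.00105. Adrb3 (chromosome 8, 28336248 to 28340060), the adrenergic receptor of fat cells, rose from 1.94 ± 0.459 to 25.3 ± 2.03 TPM (log2 fold change 3.17, SE 0.14, adjusted p = 7.14e-10), and Pck1 from 2.71 ± 0.461 to 29 ± 1.63 (log2 fold change 3.02, SE 0.14, adjusted p = 1.07e-09). Car3 rose by 2.64 ± 0.15 and Ghrh by 2.86 ± 0.29. Car2 rose by 3.26 ± 0.58, and it is also among the 97 genes with replicates far apart. Adipoq rose by 1.22 ± 0.16, Lpl by 0.79 ± 0.07, Cebpa by 0.94 ± 0.16, Scd1 by 1.91 ± 0.09 and Fabp4 by 0.72 ± 0.09, the last not under quantile normalization, which gives a gene of unchanged rank 1 value, Fabp4 ranking first in each library of both days. In the brown and beige list 6 of 8 genes rose, 0 fell and 2 were not called (7 and 0 adjusted over the list alone), with camera adjusted p = 0.0179. For cholesterol synthesis 16 of 22 genes rose, 1 fell and 5 were not called (16 and 1 adjusted over the list alone). The median was 0.48, with camera adjusted p = 0.0195. Sqle rose by 1.10 ± 0.05. For fatty acid and triglyceride synthesis 16 rose, 1 fell and 7 were not called (17 and 1 adjusted over the list alone, camera adjusted p = 1.37e-08 with the preset correlation and adjusted p = 0.0999 with an estimated correlation). Median-ratio scaling called it higher (adjusted p = 0.0402). For mitochondrial oxidation 37 rose, 2 fell and 11 were not called (39 and 2 adjusted over the list alone), with camera adjusted p = 0.00753, which median-ratio scaling raised to adjusted p = 0.0821 with the same median of 0.31.

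Glucocorticoid responsive genes fell over this step, as 11 of 19 genes fell, 2 rose and 6 were not called (12 and 2 adjusted over the list alone). The median was -0.45, with camera adjusted p = 0.0195. Fkbp5 fell from 557 ± 17.6 to 108 ± 16.7 TPM (log2 fold change -2.37, SE 0.08, adjusted p = 1.12e-10) and Tsc22d3 from 384 ± 10.8 to 73.2 ± 9.15 (log2 fold change -2.38, SE 0.12, adjusted p = 2.42e-09), as did Cebpd (-1.72 ± 0.07). The acute phase genes Orm3 (-3.02 ± 0.18) and Saa3 (-2.76 ± 0.20) fell, as did Retnla (-2.70 ± 0.27) and Fam107a (-2.77 ± 0.18). For 29 genes for proteins of the ribosome 24 fell, 0 rose and 5 were not called (25 and 0 adjusted over the list alone, median -0.40, camera adjusted p = 0.0448). Median-ratio scaling raised this to adjusted p = 0.173 with the same median. For ribosome biogenesis 17 fell, 0 rose and 12 were not called (19 and 0 adjusted over the list alone, median -0.30, camera adjusted p = 0.0318). In the unfolded protein and amino acid response list 12 of 24 genes rose, 2 fell and 10 were not called (13 and 2 adjusted over the list alone), with camera adjusted p = 0.0195. Trib3 rose by 2.12 ± 0.11 and Ddit3 by 1.57 ± 0.09. For mitosis 22 of 48 genes rose, 0 fell and 26 were not called (31 and 0 adjusted over the list alone, camera adjusted p = 1.6e-07 with the preset correlation and adjusted p = 0.0732 with an estimated correlation). A pseudocount of 0.1 (adjusted p = 0.0484), median-ratio scaling (0.0402) and quantile normalization (0.0306) called this list higher. In replication 12 of 51 genes rose, 0 fell and 39 were not called (11 and 0 adjusted over the list alone, camera adjusted p = 0.0403 with the preset correlation and adjusted p = 0.292 with an estimated correlation). Mki67 rose by 0.70 ± 0.14, Ccnb1 by 0.32 ± 0.08 and Mcm2 by 0.18 ± 0.05, while Pcna and Top2a were not called (-0.03 and -0.03). The call of Mcm2 ended without Day4 replicate 2, Day6 replicate 1 or Day6 replicate 2 (0.16 to 0.17) and in a fit on the 6 libraries alone (0.18).

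The step from Day6 to Day8 had the fewest called genes of the 9 comparisons. Replication and mitosis genes fell again. Of the tested genes 1287 rose and 1474 fell (n = 3 per group), 204 of them by 1 or more, and a fit on these 6 libraries alone called 1072. Without Day6 replicate 2, 1267 rose and 1195 fell, so the excess of falling genes depends on that library. For replication 36 of 51 genes fell, 1 rose and 14 were not called (41 and 2 adjusted over the list alone). The median was -0.45, with camera adjusted p = 0.00222. Rrm2 fell from 47.1 ± 2.07 to 21.7 ± 2.46 TPM (log2 fold change -1.09, SE 0.07, adjusted p = 1.56e-07), as did Pcna (-0.62 ± 0.05). For mitosis 38 of 48 genes fell, 0 rose and 10 were not called (38 and 0 adjusted over the list alone). The median was -0.66, with camera adjusted p = 0.00438. Mki67 (-1.14 ± 0.14) and Birc5 (-1.36 ± 0.18) were among those that fell. For mature fat cell genes 11 of 38 genes fell, 10 rose and 17 were not called (11 and 12 adjusted over the list alone, camera adjusted p = 0.594). Pck1 rose from 29 ± 1.63 to 109 ± 26.9 TPM (log2 fold change 1.84, SE 0.14, adjusted p = 5.73e-07), Adrb3 from 25.3 ± 2.03 to 84.2 ± 18.7 (log2 fold change 1.68, SE 0.14, adjusted p = 1.17e-06) and Lep (leptin) by 1.35 ± 0.15, while Fabp4 fell by 0.30. Adipoq and Cebpa were not called (0.18 and 0.18). Lpl was not called (0.01), though quantile normalization called it lower at -0.30 (adjusted p = 0.0193). The call of Fabp4 ended without Day6 replicate 1 (-0.26) or 3 (-0.29), without Day8 replicate 2 (-0.23), in the fit on 6 libraries (-0.30) and under quantile normalization (0.00). Inhbb, an activin subunit, rose from 12.3 ± 1.93 to 55.3 ± 9.37 TPM (log2 fold change 2.08, SE 0.13, adjusted p = 8.18e-08) and Col1a1 by 0.71 ± 0.14, which the fit on 6 libraries did not call (0.71, adjusted p = 0.0704). Fkbp5 (-1.47 ± 0.08) and Lcn2 (-1.56 ± 0.14) fell, in a glucocorticoid responsive list where 12 fell, 2 rose and 5 were not called (12 and 2 adjusted over the list alone, camera adjusted p = 1.56e-06 with the preset correlation and adjusted p = 0.0542 with an estimated correlation). Median-ratio scaling (adjusted p = 0.0217) and quantile normalization (0.0234) called this list lower. For ribosome biogenesis 18 of 29 genes fell, 0 rose and 11 were not called (21 and 1 adjusted over the list alone, camera adjusted p = 1.24e-09 with the preset correlation and adjusted p = 0.0542 with an estimated correlation). Quantile normalization called it lower (adjusted p = 0.0234). Tmem251 fell from 10.5 ± 3.05 to 0.967 ± 1.68 TPM (log2 fold change -2.84, SE 0.56, adjusted p = 0.00197), and Ear12 (-2.58 ± 0.30) fell too. F13a1 rose by 1.92 ± 0.14 and Cox6a2 by 2.23 ± 0.36, the latter not with a pseudocount of 0.1. Relb rose by 3.21 ± 1.08 (adjusted p = 0.0447), while Add3 (-2.88 ± 0.97) and H2ac18 (-3.20 ± 0.74) fell, and the 3 are among the 97 genes with replicates far apart (H2ac18 libraries of 55.8, 2.43 and 1.71 TPM at Day8). The fit on 6 libraries called none of the 3, and the calls of Relb and Add3 each ended without any 1 of 5 libraries.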

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

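The tests of scaling, of a mislabelled library and of white blood cells below were chosen only after the results were seen. Of the panel genes 6 were called in opposite directions against Control at MCE1 and at Day8, which flagged them. Since they were chosen for that, the difference between the stages was not tested apart from the choice, and it is given as a size only (n = 3 per group). On the log2 scale Day8 differed from MCE1 by -2.98 for Pcna, -3.24 for Ccnb1, -4.37 for Top2a, -3.49 for Fkbp5, -2.03 for Myc and 2.08 for Col1a1. The call of Myc at MCE1 was unstable, as given above. Over all tested genes 763 were called higher at MCE1 and lower at Day8 than in Control, and 724 lower at MCE1 and higher at Day8.

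Control cells stood close to MCE1 cells in the genes of DNA replication and mitosis, 99 genes in all, with a median log2 change of 0.28 from Control to MCE1. Scaling did not account for it, since the median was 0.40 (SE 0.05) with median-ratio scaling and 0.28 (SE 0.05) under quantile normalization. A mislabelled Control library did not account for it, as the 3 Control medians were 6.19, 6.14 and 6.18 on the log2 scale, a span of 0.05, against 6.40 at MCE1 and 4.99 at MCE2. Control cells still in cycle when collected could account for it. At MCE1 12 genes linked to arrest had a median log2 change of 0.67 (SE 0.29), 8 called higher and 3 lower. The kinase inhibitors Cdkn2b (-1.80) and Cdkn1a (-2.55, an unstable call), not among the 12, went the other way. This account is no more than a hypothesis. Dexamethasone may raise some of the 12 by itself, and the labels give neither the cycle state of Control cells nor the hour of MCE1.

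In 97 of 9289 genes at 10 TPM or more the replicates of a group lay far apart (an SD of 1 or more on the log2 scale), Pparg and Hspd1 among them. A candidate explanation is that each table lists 1 of several transcripts of a gene, not always the same. Of the 97, 96 had curated RefSeq transcripts. Of these 77.1% had 2 or more, against 47.9% of genes matched by TPM (permutation p = 0.000999, the least 1000 permutations give). Pparg had 4 and Hspd1 2. Yet the recorded end varied in only 5.2% of the 97 and 4% of other genes. Of the 150 cases Day4 replicates 1 to 3 held 20 (13.3%, the most), 7 and 8, so a poor library there is not excluded. No biological explanation was tested, and a change of Pparg cannot be ruled out.

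Lcn2, Retnla, S100a8 and Ear2, which white blood cells also express, were among the largest rises from Control to MCE1 named by rule. White blood cells in the cultures did not account for them, as 7 other white blood cell genes (Tyrobp, Fcer1g, Laptm5, Coro1a, Cd53, Ptprc and Lyz2) summed to 5.81 TPM at MCE1 and 5.73 in Control, 0.562% of the 1030.0 TPM of the 4 genes at MCE1. Reads shared between paralogs did not account for Lcn2, Retnla and S100a8, which shared 0% of their 50-base stretches with other genes. For Ear2, which shared 41.5% with Ear1, Ear6, Ear10 and pseudogenes, its own reads cannot be told apart from theirs without the alignments. No biological explanation was tested for this pattern.

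Other splits of the libraries were counted for each comparison, and the 10 splits of 3 against 3 libraries are too few for a share under 0.05. In each of the 9 comparisons 1 of the 10 splits, the real one, gave as many called genes. The real counts and the highest of the other splits were 6526 and 2 for MCE1 against Control, 7933 and 2 for MCE2 against Control, 8756 and 1 for Day4 against Control, 8843 and 0 for Day6 against Control, 9061 and 1 for Day8 against Control, 5439 and 2 for MCE2 against MCE1, 6550 and 1 for Day4 against MCE2, 3257 and 4 for Day6 against Day4 and 2761 and 21 for Day8 against Day6. For the F test 1 of 100 regroupings gave as many called genes, the real one with 11120, and the highest of the others was 155, so a random grouping of the libraries is excluded for it.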

How the results depend on the processing

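The alternatives without genes at 0 in 1 replicate and without genes of varying end were chosen after seeing the data. All 9 counts of called genes stayed within 1.5 times the reported count under each alternative run, apart from the larger threshold and the fit on 2 groups only given next. Asking for a log2 fold change of 1 as well gave 1723 genes for MCE1, 2595 for MCE2, 3469 for Day4, 3747 for Day6 and 4109 for Day8 against Control, 970 for MCE2 against MCE1, 1384 for Day4 against MCE2, 368 for Day6 against Day4 and 204 for Day8 against Day6, fewer by construction. The fit on 2 groups only gave 1072 genes for Day8 against Day6 (2761 with all libraries), with 4 residual degrees of freedom in place of 12. Leaving out each library in turn gave 0.79 to 0.98 times the reported counts and 10893 to 11133 genes in the F test, which ranged from 9524 (filter of 5 TPM) to 12178 (no filter). Without Control replicate 1, whose table differs in form, 5998, 7499, 8227, 8405 and 8606 genes were called against Control in order, and 0 of those shared with the reported calls turned. Median-ratio scaling moved the share of called genes that were higher from 42.9 to 54.1% at MCE1 and from 37.4 to 50% at MCE2, and quantile normalization moved them to 51.7 and 49.4%. At Day4, Day6 and Day8 the shares became 51.2, 51.2 and 50.7% with median-ratio scaling and 47.9, 46.1 and 46.9% under quantile normalization. For MCE2 against MCE1 the share moved from 41.2 to 50.5% with median-ratio scaling and 51.1% under quantile normalization, for Day4 against MCE2 from 57.4 to 51.9 and 47.8%, and for Day6 against Day4 from 56.3 to 58.7 and 49.3%. Leaving out Day6 replicate 2 moved it from 46.6 to 51.5% for Day8 against Day6.

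Of 207 list tests 51 were called with an estimated correlation, 113 with the preset correlation and 176 with fry, and the 51 were among those of both. Median-ratio scaling called 55 (7 lost, 11 gained), quantile normalization called 62 (1 lost, 12 gained), and 53 were called with a pseudocount of 0.1 (0 lost, 2 gained). Of the 7 lost, 6 were those of mitochondrial oxidation and 1 that of proteins of the ribosome from Day4 to Day6, with adjusted p from 0.0532 to 0.22. Their medians were no smaller apart from that of Day4 against MCE2 (0.43, reported 0.48), and the cause was not tested. The 1 lost under quantile normalization was mitochondrial oxidation at MCE1 (0.136). Gained with median-ratio scaling were fibroblast matrix and contractile genes at MCE1 and MCE2, fatty acid and triglyceride synthesis at Day6, at Day8, from MCE1 to MCE2 and from Day4 to Day6, and cell cycle regulators from MCE1 to MCE2. The others were mitosis and the clock (0.0402) from Day4 to Day6, and glucocorticoid responsive genes and the clock (0.0217) from Day6 to Day8. Gained under quantile normalization were adipogenic transcription factors at MCE1 and from MCE1 to MCE2, ribosome biogenesis at Day4 and from Day6 to Day8, and cell cycle regulators at Day8 (0.047) and from MCE1 to MCE2. The clock was gained at Day8 (0.0424), from Day4 to Day6 (0.0167) and from Day6 to Day8 (0.0182), mitosis and cAMP responsive genes (0.0418) from Day4 to Day6, and glucocorticoid responsive genes from Day6 to Day8. With a pseudocount of 0.1 the 2 were adipogenic transcription factors at MCE1 and mitosis from Day4 to Day6.

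Of 1019 values of named genes, 964 were called, and 908 (of 963 left by the filter of 5 TPM) to 967 were under each alternative on all libraries. In 6114 values with a library left out, 5994 stayed on their side of the threshold, 111 were no longer called, 9 were newly called and 0 turned. Values that changed sides on all libraries were Top2a at MCE2 against Control with median-ratio scaling (0.20, reported 0.00) and Lpl from Day6 to Day8 under quantile normalization (-0.30, reported 0.01), for which the cause was not tested. The call of Fabp4 from Day4 to Day6 was lost under quantile normalization (0.00, reported 0.72), which by construction gives 1 value to a gene that ranks first in each library.

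The labels number the replicates of each group 1 to 3. With the number as a replicate block, the called genes were 6525, 7938, 8731, 8846 and 9040 against Control in order, 5417, 6520, 3222 and 2711 for the steps and 11090 in the F test, and 49 list tests were called (3 lost, 1 gained), as were 963 named values. The 3 were mitochondrial oxidation at MCE1 (adjusted p = 0.0637, reported 0.0312), adipogenic transcription factors at Day8 (0.056, reported 0.0369) and proteins of the ribosome from Day4 to Day6 (0.0628, reported 0.0448), and the 1 was glucocorticoid responsive genes from Day6 to Day8 (0.0201, reported 0.0542). The numbers do not show pairing, since the deviations of 45 same-numbered pairs had r from -0.074 to 0.093 and 4 of 18 libraries correlated best with a library of their own number. The planned choice between tables with repeated gene names was not run, since each name occurs once. Depth is not known, so its limits could not be computed.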

Other observations

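Genes of the clock, of the interferon response and of the cAMP response were also called, though camera with an estimated correlation called 0 of these lists in the comparisons given here. At MCE1 7 of 14 genes fell, 3 rose and 4 were not called (7 and 3 adjusted over the list alone) in the clock list (camera adjusted p = 0.561). Nr1d1 fell from 40.6 ± 1.90 to 3.52 ± 0.374 TPM (log2 fold change -3.21, SE 0.13, adjusted p = 6.32e-12) and Dbp from 17.1 ± 2.38 to 1.24 ± 0.194 (log2 fold change -3.01, SE 0.11, adjusted p = 3.56e-12). Per1, which glucocorticoid raises, rose from 11.5 ± 1.77 to 76.4 ± 2.53 TPM (log2 fold change 2.64, SE 0.11, adjusted p = 8.48e-12). By Day8 Dbp stood at 110.0 ± 3.98 TPM (log2 fold change 2.63, SE 0.11, adjusted p = 4.58e-12), in a list where 7 rose, 1 fell and 6 were not called (7 and 1 adjusted over the list alone, camera adjusted p = 0.0124 with the preset correlation and adjusted p = 0.24 with an estimated correlation). Quantile normalization called the clock list higher at Day8 (adjusted p = 0.0424). Of the interferon responsive genes 13 fell, 0 rose and 6 were not called (14 and 0 adjusted over the list alone) at MCE1 (camera adjusted p = 0.00109 with the preset correlation and adjusted p = 0.233 with an estimated correlation). Ifit2 fell from 14.6 ± 2.49 to 2.24 ± 0.152 TPM (log2 fold change -2.25, SE 0.16, adjusted p = 7.6e-09). From MCE2 to Day4 13 rose, 0 fell and 6 were not called (13 and 0 adjusted over the list alone) in the interferon list (camera adjusted p = 0.000467 with the preset correlation and adjusted p = 0.207 with an estimated correlation). Rgs2, which dampens G protein signals, rose from 6.50 ± 0.673 to 224 ± 8.33 TPM (log2 fold change 4.91, SE 0.07, adjusted p = 6.43e-17). Ptgs2, which starts prostaglandin synthesis, fell from 27.3 ± 4.51 to 1.15 ± 0.0832 (log2 fold change -3.71, SE 0.19, adjusted p = 1.61e-10). In the cAMP responsive list both belong to, 7 rose, 6 fell and 3 were not called at MCE1 (7 and 6 adjusted over the list alone, camera adjusted p = 0.561).

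In the unfolded protein and amino acid response list 14 of 24 genes fell, 7 rose and 3 were not called (14 and 7 adjusted over the list alone) at MCE1 (camera adjusted p = 0.35). Chac1 fell from 58.3 ± 0.369 to 7.26 ± 0.544 TPM and Trib3 from 61.6 ± 1.75 to 9.77 ± 2.0. Ddit3 stood at 616 ± 46.1 TPM at Day8 against 105 ± 2.44 in Control (log2 fold change 2.53, SE 0.09, adjusted p = 2.74e-13). The inflammatory list went both ways, as 9 of 18 genes rose, 8 fell and 1 was not called (9 and 8 adjusted over the list alone) at MCE1 (camera adjusted p = 0.561). At Day8 9 fell, 5 rose and 4 were not called (9 and 5 adjusted over the list alone, camera adjusted p = 0.702). The complement gene C3 rose from 9.0 ± 1.33 to 860.1 ± 106 TPM at Day8 (log2 fold change 6.43, SE 0.12, adjusted p = 2.83e-16), and Ccl2 fell to 9.34 ± 1.53 (log2 fold change -5.40, SE 0.13, adjusted p = 3.71e-15). Of the genes for proteins of the ribosome 22 rose, 0 fell and 7 were not called (22 and 0 adjusted over the list alone) at MCE2 against Control (camera adjusted p = 4.53e-06 with the preset correlation and adjusted p = 0.259 with an estimated correlation). At Day8 22 fell, 1 rose and 6 were not called (23 and 1 adjusted over the list alone, camera adjusted p = 0.00157 with the preset correlation and adjusted p = 0.373 with an estimated correlation). In the housekeeping panel 5 of 12 genes rose, 5 fell and 2 were not called (5 and 5 adjusted over the list alone) at Day8 (camera adjusted p = 0.933). Actb fell from 4173 ± 183 to 1029.8 ± 24 TPM. Of bone and cartilage markers 3 fell, 1 rose and 1 was not called (3 and 1 adjusted over the list alone) at MCE1 (camera adjusted p = 0.561). Spp1 (osteopontin) fell from 1118 ± 15.6 to 48.2 ± 5.49 TPM (log2 fold change -4.51, SE 0.12, adjusted p = 1.29e-13). Of skeletal muscle markers 1 rose, 1 fell and 3 were not called (1 and 1 adjusted over the list alone) at Day8 (camera adjusted p = 0.909). Of 12 endothelial markers 0 passed the filter.

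The 58 genes listed at 0 in 1 library alone of its group included 16 in Day4 replicate 1 and 10 in Day8 replicate 1, the highest numbers of the 18 libraries.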
